A study of Mus musculus with 3 samples.

How the data were processed

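The samples were 3 RNA-seq libraries of macrophages sorted from the kidneys of 3 C57BL/6J mice, which the labels name as separate animals. Per the labels' protocols, mice received PBS intravenously and kidneys were taken 1 h later and digested for 30 min at room temperature with DNase, collagenase D and dispase. Macrophages were then sorted by flow cytometry. Complementary DNA was amplified with SMART-seq v4, a kit for very small amounts of RNA that copies and amplifies full-length transcripts. From 10 ng of amplified cDNA, libraries were made with a Kapa kit and 8 cycles of PCR, per the labels' protocols. Amplification copies molecules without identifiers, so read counts are not counts of molecules, and the intervals and floors given here cover counting error only.

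The deposited file is one table of 14811 genes with an identifier, a symbol and a column per mouse. Its values are a normalised signal: per the submitters' processing notes, the authors counted reads per gene with HTSeq 0.5.4 and scaled the counts with DESeq 1.18.0, on the mouse build mm9. The aligner, the annotation and the rule for keeping rows are not given in the sources used here. The values themselves show more. The lowest deposited value is exactly 1 in every library, and after subtraction of 1, 100% of the values are whole multiples of a step per library (tolerance 0.05 of a step). This is the pattern of a count divided by a size factor, with 1 added. The size factors obtained from the steps were 1.24, 1.80 and 1.42 for mice 1, 2 and 3. Their geometric mean was 1.47, while size factors computed from these 3 libraries alone were 0.868, 1.27 and 0.991.

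The added 1 was removed before any analysis, a choice made after the values were seen. The design fixed beforehand spoke of deposited values of 10 or more, and the count under that wording is given in the closing section. Reads per gene were obtained as the value divided by the step, which gave 50951549, 56718534 and 50646558 reads over the listed genes. One read is worth 0.806, 0.555 and 0.705 normalised reads in mice 1, 2 and 3, and the floor of 3 reads is 2.42, 1.66 and 2.11. The 3 libraries were compared before averaging: of 12465 genes with at least 5 reads expected in each library, 98.1% differed beyond Poisson noise, so no library was a copy of another. Of the symbols, 20 had been turned into dates, and 3 were duplicates. The reference annotation at hand, GENCODE M21, belongs to another build than the notes name. It was used only for exon lengths by gene identifier, which covered 99.6% of the genes, and no coordinates are given.

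With a single group there was no comparison between conditions. Levels are means ± SD of normalised read counts. On the log2 scale a pseudocount of 1 was added, so log2 differences and ratios are on the log2(value + 1) scale and understate differences of low genes. For each of 40 gene lists, fixed with the 32 gene pairs before the data were examined, the median over members of the mean log2 level was compared with 100000 random lists of the same size from genes above 0 in any library (two-sided permutation test across genes, Benjamini-Hochberg adjustment over 37 lists with at least 3 such members, a minimum set after the data were seen). List members at 0 in every library were left out of the tested medians, which raises the median of a list that has them. They entered, as did all rows for the random lists, in the alternative with all rows. The same was repeated in each library. List spread was compared with 10000 random lists matched on mean level in 20 bins (one-sided, 35 lists with at least 4 members at a mean of 10 or more). The median deviation of each list in each mouse from the mean of 3 mice was compared with 10000 lists matched in the same way (two-sided, 111 tests). Genes are not independent, and random lists do not share the coregulation of a real list. Some lists share genes. Of the list entries, 96 are genes not analysed here, which can raise a list's median, and 3 pairs were left out for the same reason.

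Within-library log2 ratios of 29 pairs were tested against 0 with limma 3.58.1 (moderated test, intercept only) in R 4.3.3, with Benjamini-Hochberg adjustment over pairs. A ratio within a library does not depend on the scaling between libraries but does depend on gene length. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The level, spread and pair tests were tested on simulated data drawn from the real genes. In those simulations, with lists of 12 members, an unadjusted p under 0.05 was reached by 4% of unchanged lists for level (13835 genes) and 6.5% for spread (11636 genes). It was reached by 100% of lists shifted by 8 log2 units. Of pairs simulated on 2180 genes, 3.5% reached it at a ratio of 1, 79% at a fold of 4 and 100% at a fold of 16.

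The genes named were fixed by rule: the 20 highest means outside mitochondrial and ribosomal protein genes, the 4 highest members of each list and any member at 0 in every library, all Fc gamma list members, all pair genes, and the 10 largest SDs of log2 among genes with a mean of 100 or more. This gave 227 genes, some of which are not reported here. Other genes named were chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 10, scaling by TMM (trimmed mean of M values) factors or to equal totals, leaving out each mouse, other minimum values, other sets for the random lists, list means, division by exon length, and another prior spread in limma. A pseudocount of 2, the deposited value of 10 and the fit of pairs with both genes above 0 were added after the data were seen. TMM factors shifted values by -0.06, 0.01 and 0.05 log2 units in mice 1, 2 and 3, and equal totals by -0.20, 0.19 and 0.01.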

Results

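The series recorded gene expression in macrophages taken from mouse kidneys at steady state. The data were 3 RNA-seq libraries from 3 C57BL/6J mice, replicates 1 to 3 of a single group. Each mouse had received phosphate-buffered saline (PBS) by intravenous injection 1 h before the kidneys were taken. Macrophages were sorted by flow cytometry after enzymatic digestion. The libraries held 50951549, 56718534 and 50646558 reads over the 14811 listed genes for mice 1, 2 and 3. The labels give no second group, so the values below are levels in these cells, ratios between genes within a library, and the spread between mice. All levels are normalised read counts, given as mean ± SD over n = 3 mice unless stated otherwise.

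The most abundant transcript outside the mitochondrial and ribosomal protein genes was Cd74, the MHC class II invariant chain, at 2283369.9 ± 219789. Cd74 took 6.38% ± 0.853 of the reads. The MHC class II chains H2-Aa (933349 ± 137227), H2-Ab1 (490446 ± 96642) and H2-Eb1 (253790.4 ± 24485) were also among the 20 most abundant, as was B2m (629891 ± 94932), the light chain of MHC class I. Further genes of these 20 included the complement C1q chains C1qb (307093 ± 45157) and C1qc (161741 ± 37183), the cathepsins Ctss (280755 ± 61249) and Ctsc (178215 ± 64991), and Lyz2 (117633 ± 18383), which encodes lysozyme. Fcer1g (150534 ± 10040.3) and Tyrobp (141597 ± 13307), the signalling adaptors of many myeloid receptors, were in this set too. The others were Tmsb4x (550106 ± 36105), Malat1 (460032 ± 184724), Fth1 (358775 ± 13143), Cst3 (290912 ± 24361), Serinc3 (234633 ± 89567), Wfdc17 (192615 ± 48242), Itm2b (120674 ± 15302) and Sepp1 (115795 ± 27272). Mitochondrial transcripts took 11.1% ± 2.87 of the reads and ribosomal protein genes 1.02% ± 0.134. The ribosomal protein share is uncertain, since these genes have many near-identical copies. The 100 most abundant genes of each library held 45.1% ± 2.99 of its reads.

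Of the 14811 listed genes, 10520 were above 0 in every mouse, 6572 reached a normalised read count of 10 in every mouse, and 976 were at 0 in every mouse. A read count of 0 allows up to 2.42, 1.66 and 2.11 normalised reads in mice 1, 2 and 3 (3 reads, counting error only). Folds given below against this floor are bounds on reads and do not cover transcripts lost before sequencing. Genes that most cells use, including Actb (70312 ± 15345), Eef1a1 (41095 ± 7715), Hprt (20409 ± 10285) and Gusb (13684 ± 8760.1), were at 10 or more in every mouse in 15 of 15 cases, and their list lay above random lists (log2 difference 4.91, adjusted p = 0.00139, permutation test). Y-linked genes were present in every library, led by Ddx3y (17349.6 ± 8760.3) and Eif2s3y (10708 ± 5164), with Uty (2748 ± 2202) and Kdm5d (2568 ± 2615) lower (log2 difference 5.55, adjusted p = 0.0277, permutation test). The call of this list was lost without mouse 1 (log2 difference 4.78, adjusted p = 0.0624, permutation test) and per kb of exon.

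Macrophage genes stood far above the level of other genes. Of the 20 macrophage identity genes, 18 were at 1000 or more in every mouse. The highest were Ctss (280755 ± 61249), Tyrobp (141597 ± 13307), Lyz2 (117633 ± 18383) and Ptprc (96284 ± 30191), the last of which encodes the leukocyte antigen CD45. The macrophage surface marker Adgre1, which encodes F4/80, was at 28673 ± 14713, and Csf1r, the receptor for the growth factor of macrophages, at 13947 ± 5719.9. The exceptions were Itgam (491 ± 509) and Cebpb, which was at 93.6, 29.4 and 109 in mice 1, 2 and 3. The median of this list lay 7.47 log2 units above that of random lists of the same size (adjusted p = 0.000247, permutation test, resting on the smallest p that 100000 random lists can give).

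In all, 13 of the 37 tested gene lists lay above random lists, 2 lay below, and 22 did not pass the test. The median of each of the 13 was above that of random lists in 3 of 3 libraries, and the median of both lower lists was below it in 3 of 3 libraries. In single libraries, 14, 13 and 11 lists lay above and 1, 2 and 1 below random lists for mice 1, 2 and 3. Neither of the 2 lower lists was called in any library alone, so the lists below there were others, among them collecting duct genes. In lists simulated from these 13835 genes, a shift of 4 log2 units had an unadjusted p under 0.05 in 60.5% of 200 draws and a shift of 1 unit in 11%, so a list that was not called may still differ. With random lists drawn only from genes detected in every mouse, 7 of the 13 calls were lost: complement receptors, Toll-like receptors, iron handling, interferon-stimulated, NF-kB, sex-linked and ubiquitously used genes.

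**Figure D1:**
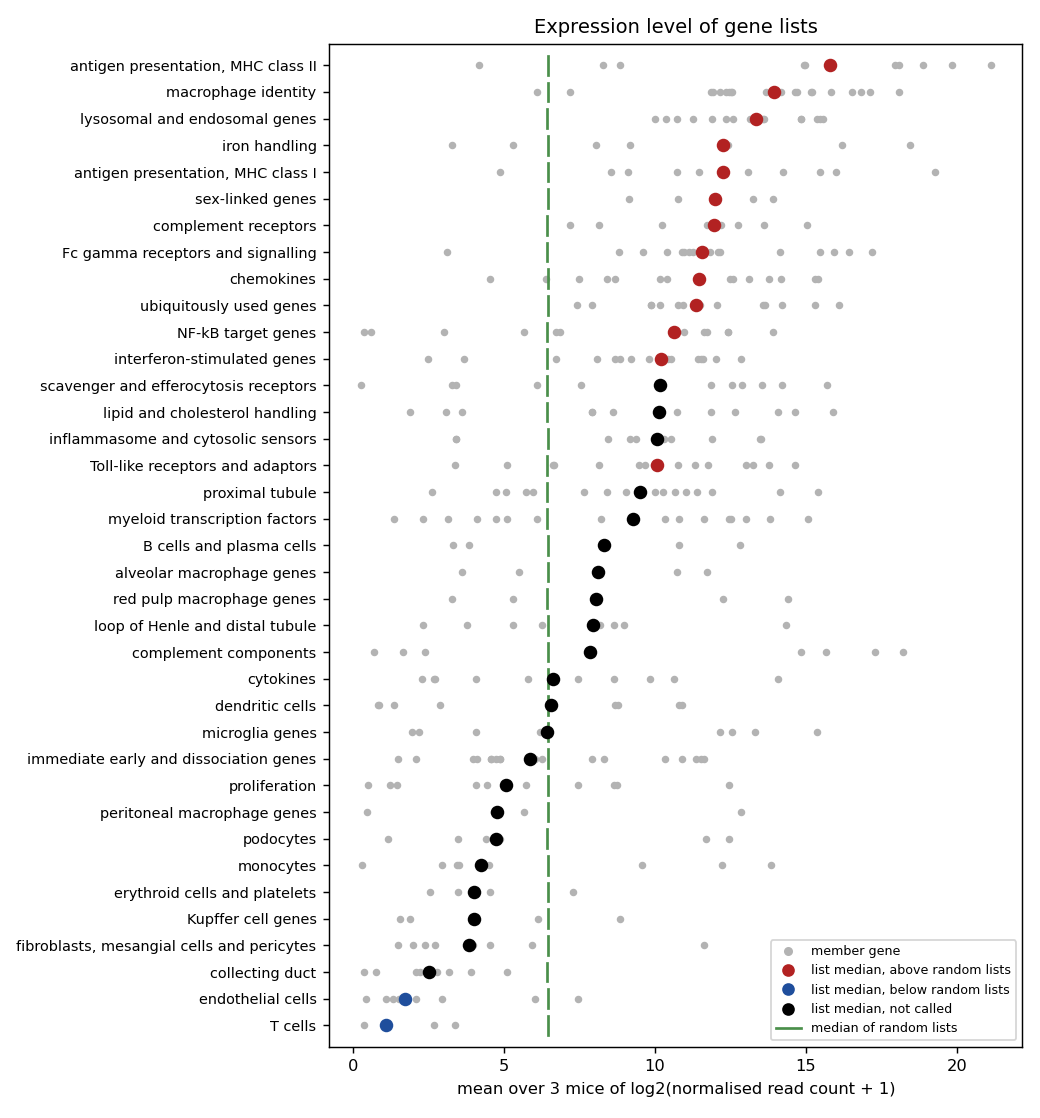
Expression level of the 37 tested gene lists in kidney macrophages, as the mean over 3 mice of log2(normalised read count + 1). Grey points are member genes, large points are list medians (red above, blue below and black not distinguished from random lists), and green marks are medians of random lists. The 13 red lists include MHC class II, macrophage identity and lysosomal genes, and the 2 blue lists are endothelial and T cell genes.

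Fc gamma receptors, which bind the constant part of IgG, and their signalling genes took 1.10% ± 0.0299 of the reads. The activating receptors Fcgr3 (87369 ± 11138) and Fcgr4 (63665 ± 15445) and the inhibitory receptor Fcgr2b (45420.3 ± 10211) were all abundant, while the high-affinity receptor Fcgr1 (4589.6 ± 783) was lower. The signalling chain Fcer1g, which the activating receptors use, was at 150534 ± 10040.3. Of the 16 genes in the Fc gamma receptor and signalling list, 10 were at 1000 or more in every mouse, and the list lay above random lists (log2 difference 5.11, adjusted p = 0.000863, permutation test). Among signalling genes that act downstream, those with higher means included Lyn (20837 ± 13304), Inpp5d (4443 ± 1444), Syk (2654 ± 1893), Btk (2621 ± 2613) and Cbl (2462 ± 331), of which Inpp5d encodes the inhibitory phosphatase SHIP1. Plcg2 (796 ± 241), Vav1 (538 ± 333) and Fgr (24.8 ± 38.6) were lower. The neonatal receptor Fcgrt (2386 ± 1467) and the cytosolic antibody receptor Trim21 (2299 ± 669) were both present.

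Within each library, Fcgr4 exceeded Fcgr1 by 13.7-fold (log2 ratio 3.78 ± 0.26 SE, adjusted p = 0.00283, limma, higher in 3 of 3 mice). Fcgr1 was below Fcgr2b in 3 of 3 mice (log2 ratio -3.29 ± 0.35 SE, adjusted p = 0.00743, limma), a call lost without mouse 2 (log2 ratio -3.15, adjusted p = 0.0517, limma). The activating receptors Fcgr3 and Fcgr4 could not be separated from Fcgr2b by the test. The Fcgr3/Fcgr2b ratio was positive in 3 of 3 mice (log2 ratio 0.96 ± 0.34 SE, adjusted p = 0.0808, limma) and the Fcgr4/Fcgr2b ratio in 2 of 3 (log2 ratio 0.49 ± 0.40 SE, adjusted p = 0.315, limma). Fcgr4 was below Fcgr3 in 3 of 3 mice, without passing the test (log2 ratio -0.48 ± 0.25 SE, adjusted p = 0.168, limma). Longer transcripts collect more reads, and after division by exon length, taken from a later annotation, the log2 ratio to Fcgr2b was 2.70 for Fcgr3 (adjusted p = 0.00934, limma) and 2.69 for Fcgr4 (adjusted p = 0.0136, limma). Over 11 alternatives the adjusted p ranged from 0.00934 to 0.257 and from 0.0136 to 0.807 (limma). An exact sign-flip test of 3 libraries cannot give a p below 0.25, two-sided.

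**Figure D2:**
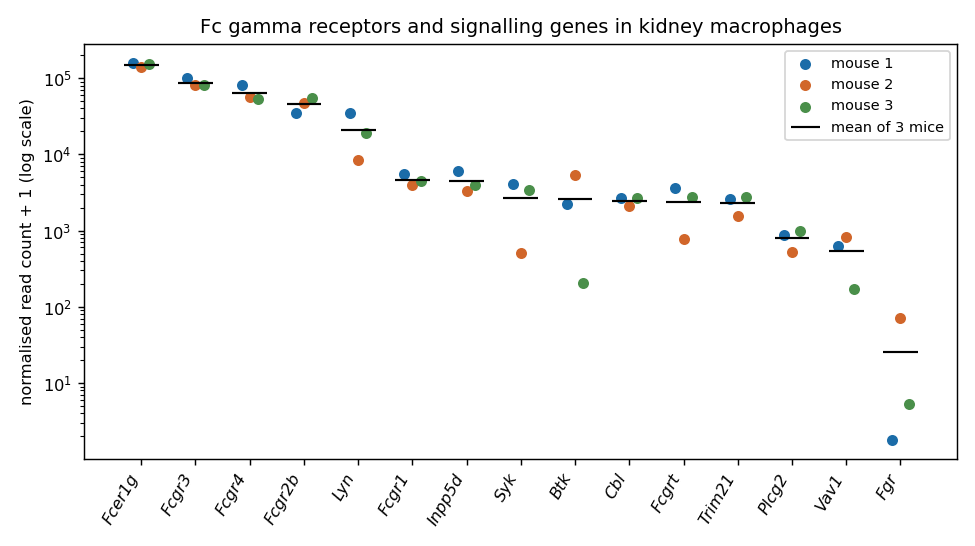
Normalised read count + 1 (log scale) of 15 Fc gamma receptor and signalling genes in kidney macrophages. Points are the 3 mice and the black line is their mean; Fcer1g, Fcgr3, Fcgr4 and Fcgr2b had the highest means, and Fgr the lowest.

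Antigen presentation genes held the top of the distribution. The MHC class II list took 12.1% ± 0.708 of all reads, and 8 of its 12 members were at 1000 or more in every mouse (log2 difference 9.34, adjusted p = 0.000247, permutation test). Besides the class II chains, the peptide-loading chain H2-DMa was at 56783 ± 5263 and the costimulatory molecule Cd86 at 31611 ± 6422. The related Cd80 was at 0 in every mouse, at least 12307-fold below Cd86 against a floor of 3 reads per library. The class II transactivator Ciita was at 42.2 ± 40.9. In the MHC class I list, B2m (629891 ± 94932), H2-K1 (68317 ± 24233), H2-D1 (46293 ± 14332) and Psmb8 (20154 ± 6431) were highest (log2 difference 5.80, adjusted p = 0.000555, permutation test). H2-Ab1 exceeded H2-K1 by 7.44-fold within a library (log2 ratio 2.90 ± 0.28 SE, adjusted p = 0.00685, limma, 3 of 3 mice). MHC genes have close relatives, so their separate values are uncertain.

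Complement genes were split. Besides C1qb and C1qc, C1qa (52143 ± 11609) was high, where C1q starts the classical pathway. Cfp (459.6 ± 594) and Cfb (220.4 ± 37.1) were low, and C1s1 was at 0 in every mouse. The list of complement components as a whole did not pass the test (log2 difference 1.41, adjusted p = 0.594, permutation test). It was called above random lists without mouse 1, with list means, and with random lists from genes at 10 or more in every library. Complement receptors lay above random lists (log2 difference 5.52, adjusted p = 0.00288, permutation test), with C3ar1 (37494 ± 22942), C5ar1 (12543 ± 1104), Cr1l (7904 ± 4391) and Cd93 (5172 ± 2909) leading. C5ar1 was below C3ar1 in 3 of 3 mice, without passing the test (log2 ratio -1.41 ± 0.51 SE, adjusted p = 0.0808, limma).

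Genes of innate sensing were present at intermediate levels. The Toll-like receptor list lay above random lists (log2 difference 3.61, adjusted p = 0.0326, permutation test), led by the lipopolysaccharide co-receptors Cd14 (27230.2 ± 12862) and Ly96 (14214 ± 2256) with Tlr4 (12639.5 ± 11280.1), and by the sensor of single-stranded RNA Tlr7 (9839 ± 2471). Tlr7 exceeded Tlr9 (log2 ratio 8.12 ± 1.83 SE, adjusted p = 0.0396, limma, 3 of 3 mice), as did Tlr13 (log2 ratio 6.23 ± 1.69 SE, adjusted p = 0.0485, limma, 3 of 3 mice), where Tlr9 varied widely (285 ± 484). Tlr4 exceeded Tlr2 (log2 ratio 3.04 ± 0.83 SE, adjusted p = 0.0485, limma, 3 of 3 mice), a call lost per kb of exon. With a pseudocount of 0.1 the Tlr13/Tlr9 and Tlr4/Tlr2 ratios were no smaller, but the adjusted p rose above 0.05 and the calls were lost. Without one mouse, calls were lost for Tlr7/Tlr9 (log2 ratio 6.86, adjusted p = 0.166 without mouse 1, log2 ratio 7.14, adjusted p = 0.147 without mouse 2, limma), Tlr13/Tlr9 (log2 ratio 4.75, adjusted p = 0.177 without mouse 1, log2 ratio 5.70, adjusted p = 0.192 without mouse 2, limma) and Tlr4/Tlr2 (log2 ratio 2.65, adjusted p = 0.192 without mouse 2, log2 ratio 2.46, adjusted p = 0.130 without mouse 3, limma). Of the inflammasome and cytosolic sensor genes, Casp1 (11758 ± 4354), Pycard (11533 ± 816), Ifih1 (5004 ± 3864) and Ddx58 (2385 ± 1999) were highest and Nod1 was at 0 in every mouse, and the list did not pass the test (log2 difference 3.62, adjusted p = 0.0791, permutation test). Nlrp3 (465 ± 424) was below Aim2 (1615 ± 1451) in 3 of 3 mice (log2 ratio -1.62 ± 0.39 SE, adjusted p = 0.0419, limma). This call was lost without each mouse in turn (log2 ratio -1.57, adjusted p = 0.177, log2 ratio -1.32, adjusted p = 0.144 and log2 ratio -1.98, adjusted p = 0.0579 without mice 1, 2 and 3, limma), when only pairs with both genes above 0 were fitted, and with the prior spread from all genes (0.0275 to 0.262 over 11 alternatives).

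Chemokine transcripts were abundant in the sorted cells. Cxcl16 (43888 ± 9909.8), Ccl6 (42262 ± 15592), Ccl4 (23962 ± 21476) and Ccl9 (14098 ± 2229) led a list that lay above random lists (log2 difference 5.02, adjusted p = 0.000863, permutation test), while Ccl17 and Ccl22 were at 0 in every mouse. Ccl3 (8604 ± 8220.1) exceeded Ccl2 (5303 ± 6311) in 3 of 3 mice without passing the test (log2 ratio 1.02 ± 0.32 SE, adjusted p = 0.0670, limma). The Cxcl2/Cxcl1 ratio went in different directions in the 3 mice (log2 ratio -2.03 ± 2.79 SE, adjusted p = 0.518, limma).

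Among cytokines, Il1b stood out at 17318 ± 2409, followed by Igf1 (2195 ± 1557), Pdgfb (943 ± 294) and Tgfb1 (680.1 ± 832). Il1a, Il6, Il10, Il12b and Il1rn were at 0 in every mouse. Il1b was at least 6333-fold above Il1rn, the gene of the receptor antagonist, against a floor of 3 reads per library. Tnf (96.5 ± 108) was at least 5-fold above Il10 on the same floor. The cytokine list did not pass the test (log2 difference 0.17, adjusted p = 0.978, permutation test) over its 10 members above 0. With the members at 0 and all rows it lay on the other side, without passing (log2 difference -3.27, adjusted p = 0.0896, permutation test).

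Response genes were mixed. NF-kB target genes lay above random lists (log2 difference 4.18, adjusted p = 0.0255, permutation test), with Cd83 (19435 ± 12376), Nfkbiz (6209 ± 3878), Nfkbia (5763 ± 2283) and Birc3 (4732 ± 3501) highest. This call was lost without mouse 1 (log2 difference 3.58, adjusted p = 0.0624, permutation test), per kb of exon and with list means. Interferon-stimulated genes lay above random lists as well (log2 difference 3.77, adjusted p = 0.0266, permutation test), with Ifit3 (4508 ± 2303), Usp18 (3441 ± 2230.3) and Oas2 (3421 ± 2901) among the highest, and this call was lost without mouse 2 (log2 difference 3.20, adjusted p = 0.0933, permutation test). Immediate early and dissociation genes, which can be induced by tissue digestion, did not pass the test (log2 difference -0.57, adjusted p = 0.768, permutation test). Their highest members were Zfp36 (4931 ± 4586), Hsp90aa1 (3455 ± 2013), Dusp1 (3276 ± 2807) and Dnajb1 (2009 ± 704). Proliferation genes did not pass it either (log2 difference -1.39, adjusted p = 0.594, permutation test): Pcna was at 5625 ± 400.1, Bub1 (1256 ± 1381), Cdk1 (802 ± 993) and Mcm5 (690.1 ± 1193) followed, and Ccnb1 and Aurkb were at 0 in every mouse.

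Lysosomal and iron handling genes were high. All 18 lysosomal and endosomal genes were at 10 or more in every mouse and 14 at 1000 or more (log2 difference 6.91, adjusted p = 0.000247, permutation test), with Ctsb (55264 ± 34416), Lamp2 (46954 ± 16781) and Ctsz (30288 ± 9331) among the highest. Iron handling genes lay above random lists (log2 difference 5.81, adjusted p = 0.00137, permutation test), led by the ferritin chains Fth1 (358775 ± 13143) and Ftl1 (74349.7 ± 5861), then Blvrb (5637 ± 1497) and the iron exporter Slc40a1 (5422 ± 3092). The scavenger and efferocytosis list did not pass the test (log2 difference 3.74, adjusted p = 0.0533, permutation test), although Cd36 (53751 ± 8404), Axl (21551 ± 11371), Mrc1 (12380.1 ± 4411) and Msr1 (8779 ± 5424) were highest among those named, and Trem2 was at 0 in every mouse. This list was called above under some alternatives, such as list means and division by exon length. Mrc1 exceeded Cd163 (log2 ratio 10.26 ± 2.33 SE, adjusted p = 0.0396, limma, 3 of 3 mice), where Cd163 was at 344 in mouse 2 and near or at 0 in both others. The adjusted p of this pair rose above 0.05 with a pseudocount of 0.1, where the ratio was no smaller, and without mouse 1 or mouse 3 (log2 ratio 9.06, adjusted p = 0.172 and log2 ratio 8.59, adjusted p = 0.0985, limma). Mertk (4212 ± 2359) was below Axl in 3 of 3 mice without passing the test (log2 ratio -2.36 ± 0.79 SE, adjusted p = 0.0743, limma). In the lipid list, Apoe (60799 ± 2963), Ch25h (27353 ± 10814), Lpl (17398 ± 2901) and Plin2 (7449.9 ± 4169) were highest, and the list did not pass the test (log2 difference 3.70, adjusted p = 0.0535, permutation test). Apoe was at least 24432-fold above Trem2 against a floor of 3 reads per library.

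Maf (35618 ± 10907), Zeb2 (16151 ± 8384), Id2 (8818 ± 3725) and Spi1 (5925 ± 837) led the myeloid transcription factors, a list that did not pass the test (log2 difference 2.84, adjusted p = 0.104, permutation test). Irf8 (1447 ± 862) exceeded Irf4 (41.1 ± 71.1) in 3 of 3 mice (log2 ratio 8.03 ± 2.12 SE, adjusted p = 0.0485, limma), a call lost without mouse 1 (log2 ratio 7.04, adjusted p = 0.198, limma) or mouse 3 (log2 ratio 6.41, adjusted p = 0.124, limma). Irf4 was above 0 only in mouse 2, so this ratio depends on the pseudocount, and the dendritic cell factor Zbtb46 was above 0 only in mouse 3. Adgre1 exceeded Itgax (3556 ± 1418) by 7.84-fold (log2 ratio 2.97 ± 0.40 SE, adjusted p = 0.0121, limma, 3 of 3 mice), a call lost without mouse 1 (log2 ratio 2.62, adjusted p = 0.0621, limma) or mouse 2 (log2 ratio 2.98, adjusted p = 0.0735, limma), and the Itgam/Itgax ratio did not pass the test (log2 ratio -4.54 ± 2.04 SE, adjusted p = 0.127, limma, lower in 3 of 3 mice).

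None of the 5 lists from other tissue macrophages passed the test (adjusted p = 0.506 for Kupffer cells, 0.605 for alveolar, 0.616 for peritoneal, 0.594 for red pulp macrophages and 0.989 for microglia, permutation test). The log2 differences were -2.44, 1.66, -1.68, 1.60 and -0.03. Single members were high: the microglia genes Gpr34 (10494 ± 3608), Cx3cr1 (7251 ± 5792) and P2ry12 (5327 ± 3627), the red pulp macrophage gene Vcam1 (22497 ± 7625) and the peritoneal macrophage gene Cd9 (7531 ± 2213). Others were lower, such as the Kupffer cell genes Id3 (781 ± 1333) and Clec1b (591 ± 527), the alveolar macrophage genes Pparg (2776 ± 3309) and Car4 (514 ± 878), the peritoneal macrophage genes Thbs1 (263 ± 434), Icam2 (225 ± 375) and Prg4 (162 ± 267) and the red pulp macrophage genes Hmox1 (1152 ± 1807) and Spic (633 ± 1087). Fcrls and Treml4 were at 0 in every mouse. In these 5 lists, from 4 to 10 genes were measured.

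Of the tested lists of other immune cells, only T cell genes passed the test. Their list lay below random lists (log2 difference -5.34, adjusted p = 0.0148, permutation test), with Cd247 (55.6 ± 95.8), Cd4 (39.3 ± 64.3), Foxp3 (2.96 ± 5.13) and Lck (1.68 ± 2.25) highest and Cd3e and Bcl11b at 0 in every mouse. Csf1r was at least 4463-fold above Cd3e against a floor of 3 reads per library. The T cell call was lost without mouse 2 (log2 difference -2.96, adjusted p = 0.589, permutation test), and the list was not called in any library alone. Among dendritic cell genes, Clec9a (2071 ± 1171), Batf3 (1839.7 ± 594), Clec10a (1438 ± 1332) and Dpp4 (1006 ± 1117) were highest, Cd209a and Ccr7 were at 0 in every mouse, and the list did not pass the test (log2 difference 0.11, adjusted p = 0.986, permutation test; -3.09, adjusted p = 0.191 with the members at 0 and all rows). Csf1r exceeded the dendritic cell receptor Flt3 (1.61 ± 2.79) (log2 ratio 12.82 ± 0.67 SE, adjusted p = 0.00155, limma, 3 of 3 mice), a ratio that depends on the pseudocount since Flt3 had 6 reads in mouse 1 and 0 in both others. The monocyte list did not pass the test (log2 difference -2.19, adjusted p = 0.493, permutation test), but its chemokine receptor Ccr2 was at 16766 ± 10845, with Ms4a4c (5013 ± 1658), Spn (1657 ± 2320.2) and Ly6c2 (357 ± 616) next. Cx3cr1 was below Ccr2 in 3 of 3 mice (log2 ratio -1.30 ± 0.28 SE, adjusted p = 0.0396, limma), a call that was lost without each mouse in turn (log2 ratio -1.42, adjusted p = 0.151, log2 ratio -1.36, adjusted p = 0.124 and log2 ratio -1.12, adjusted p = 0.124 without mice 1, 2 and 3, limma) and per kb of exon (adjusted p = 0.0914, limma; 0.0291 to 0.151 over 11 alternatives).

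B cell transcripts were present: Ighm (9726 ± 9416), Cd79b (3509 ± 3089), Ighd (1027 ± 940.1) and Sdc1 (126 ± 217) were the highest of 5 measured genes (log2 difference 1.85, adjusted p = 0.594, permutation test). Of the erythroid and platelet genes, Bpgm (775 ± 1222), Ppbp (567 ± 979) and Hbb-bs (72.6 ± 121) were highest, Hbb-bt was at 0, 0 and 201 in mice 1, 2 and 3, and Hba-a1 and Itga2b were at 0 in every mouse (log2 difference -2.44, adjusted p = 0.506, permutation test). Globin genes share near-identical copies, so their values are uncertain. Fewer than 3 genes above 0 were measured for neutrophils, mast cells and natural killer cells, whose lists were not tested. S100a9, Ms4a2 and Eomes were at 0 in every mouse, and Csf3r (7.56 ± 10.3), Gata2 (48.7 ± 83.7), Kit (12.1 ± 20.3) and Klrd1 (1004 ± 892) were among those above 0.

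Kidney parenchymal genes were detected in the libraries of sorted cells. The proximal tubule genes Kap (73687 ± 85899.7), Gatm (18076 ± 1267), Cyp2e1 (4904 ± 6948) and Miox (4371 ± 2966) were highest in a list that did not pass the test (log2 difference 3.08, adjusted p = 0.0785, permutation test). The list was called above random lists without mouse 3 and with list means. This list took 0.171% of the reads in mouse 1 (95% Wilson interval 0.170 to 0.172), 0.773% in mouse 2 (0.771 to 0.775) and 0.101% in mouse 3 (0.0999 to 0.102). In mouse 2 most of these reads came from Kap, which was at 35490, 172061 and 13511 in mice 1, 2 and 3. The share is therefore no even measure of the 16 genes. In mouse 2, 8594 normalised reads of the endocytic receptor Lrp2 were counted, against 1697 in mouse 1 and 122 in mouse 3, and the Csf1r/Lrp2 ratio was positive in 2 of 3 mice (log2 ratio 3.42 ± 1.74 SE, adjusted p = 0.158, limma). Of the loop of Henle and distal tubule genes, Wnk1 (22608 ± 11322), Calb1 (1554 ± 2483), Kcnj10 (549 ± 303) and Umod (546 ± 481) were highest (log2 difference 1.51, adjusted p = 0.594, permutation test). Not every high member followed the rise of the tubule list in mouse 2. Wnk1 was lowest there (23025.5, 11083 and 33715 in mice 1, 2 and 3), and the proximal tubule gene Gatm was nearly even (18406, 19146 and 16676.5). The values do not show which cells gave the Wnk1 reads, so its high level alone is no sign of tubule cells. The collecting duct list did not pass the test (log2 difference -3.93, adjusted p = 0.0657, permutation test), with Atp6v1g3 (255 ± 439.9), Scnn1g (240.1 ± 416), Aqp3 (117 ± 179.6) and Slc26a4 (52.1 ± 89.2) highest and Scnn1b at 0 in every mouse. It was called below random lists with a pseudocount of 0.1 and with list means. In mouse 2, 15 of 16 proximal tubule, 6 of 9 loop of Henle and distal tubule, 6 of 8 collecting duct and 4 of 7 podocyte genes above 0 were highest, as were 4 of 4 Kupffer cell, 3 of 4 alveolar macrophage and 7 of 10 cytokine genes. Over all 13835 genes above 0 in any mouse, 4911 were highest in mouse 2. Some lists went the other way, with 0 of 4 erythroid and platelet, 0 of 8 complement receptor and 0 of 11 MHC class II genes highest there. Mitochondrial transcripts took 10.3%, 14.3% and 8.73% of the reads in mice 1, 2 and 3.

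Endothelial genes were low. Their list lay below random lists (log2 difference -4.73, adjusted p = 0.00540, permutation test), with Kdr (602 ± 681), Emcn (69.7 ± 30.7), Eng (14.5 ± 24.4) and Tie1 (13.2 ± 22.8) highest and Tek at 0 in every mouse. Csf1r exceeded Kdr in 3 of 3 mice (log2 ratio 6.21 ± 1.47 SE, adjusted p = 0.0417, limma), a call lost without mouse 1 (log2 ratio 6.74, adjusted p = 0.160, limma) or mouse 3 (log2 ratio 7.44, adjusted p = 0.0517, limma). The endothelial call was lost without mouse 2 (log2 difference -4.18, adjusted p = 0.0861, permutation test), and the list was not called in any library alone. The podocyte list did not pass the test (log2 difference -1.69, adjusted p = 0.594, permutation test). It shares a gene with the macrophage list, and its members included Ptpro (4589 ± 4170.5) and Podxl (144 ± 233). The list of fibroblast, mesangial and pericyte genes did not pass it either (log2 difference -2.61, adjusted p = 0.363, permutation test), with Itga8 (3627 ± 1918), Dcn (354 ± 485), Cspg4 (164 ± 281) and Rgs5 (36.2 ± 61.4) highest.

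**Figure D3:**
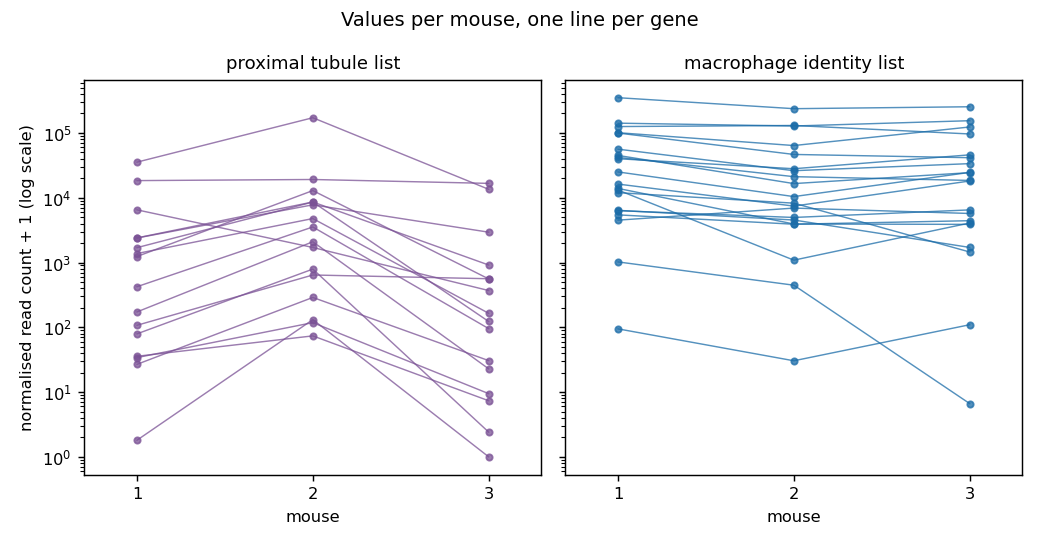
Normalised read count + 1 (log scale) in each of the 3 mice for 16 proximal tubule genes (left) and 20 macrophage identity genes (right). Each line joins the values of one gene; the mice have no order. Of the 16 tubule genes, 15 were highest in mouse 2.

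The mice differed widely in weakly and moderately expressed genes. Spearman's rho across the 13835 genes above 0 in any mouse was 0.654 between mice 1 and 2, 0.661 between mice 1 and 3, and 0.645 between mice 2 and 3. Genes are not independent replicates, so these values carry no test. The median SD of log2(normalised read count + 1) over the 6572 genes detected in every mouse was 1.17. By mean level, the median SD was 3.09 for genes from 10 to 100, 3.56 from 100 to 1000, 1.25 from 1000 to 10000, and 0.49 at 10000 or more. Among genes with a mean of 100 or more, the 10 with the largest SD of log2 were 9130008F23Rik, Irs2, Fam73b, A130051J06Rik, Mcm5, Gtf2e2, Gm37738, Rasgrf2, BC064078 and Rtca. For example, Gtf2e2, which encodes a subunit of a general transcription factor, was at 5815 in mouse 1, 7.21 in mouse 2 and 4.23 in mouse 3. Irs2, an adaptor of insulin signalling, was at 1245 in mouse 1 and at 0 in both others.

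**Figure D4:**
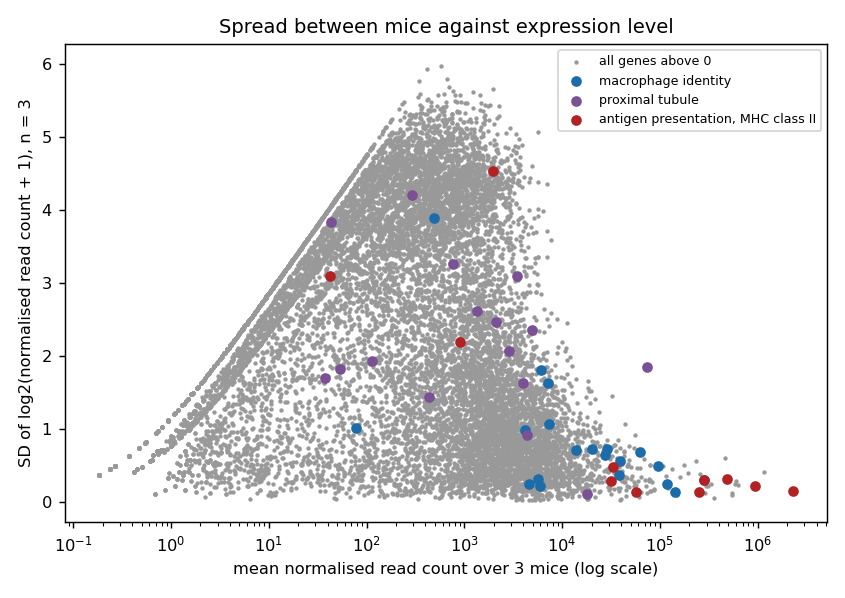
SD over 3 mice of log2(normalised read count + 1) against the mean normalised read count (log scale), one point per gene. The median SD was 3.09 for genes with a mean from 10 to 100, 3.56 from 100 to 1000 and 0.49 at 10000 or more; coloured points are the macrophage identity, proximal tubule and MHC class II lists.

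No gene list passed the test for a larger spread between mice than lists matched on level: 0 of 35 had an adjusted p under 0.05 in a permutation test, and 4 had an unadjusted p under 0.05. Chemokines had the lowest p (p = 0.00500, adjusted p = 0.175, one-sided permutation test), with a median SD of 1.71 against 0.90 in matched lists. The other 3 were interferon-stimulated, proliferation and B cell genes. In simulations on 11636 genes, a doubled SD gave an unadjusted p under 0.05 in 89% of 200 lists of 12 members. The real test was adjusted over 35 lists, some with fewer members, so it was less sensitive than this share. A list that did not pass may still vary more between mice.

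Of the 111 tests of a list's deviation in one mouse, 1 passed with adjustment over all of them: proximal tubule genes were 2.10 log2 units above the mean of the 3 mice in mouse 2 (adjusted p = 0.0222, permutation test). With adjustment within each mouse, erythroid and platelet genes in mouse 3 (4.68, 4 of 4 highest) and proximal tubule genes in mouse 3 (-1.88) passed as well (adjusted p = 0.0296 for both, and 0.0592 over all tests, permutation test). Deviations are taken from the mean of the same 3 mice, so a list high in one mouse is pushed down in the others. The low tubule value of mouse 3 is therefore not independent of the high value of mouse 2. Other lists lay above their mean in mouse 2 without passing, among them Kupffer cell (3.46), alveolar macrophage (3.33), collecting duct (2.39), cytokine (2.12), B cell (1.93), loop of Henle (1.63), podocyte (1.25) and stromal (1.25) genes. Lists matched to these on level lay above it as well, for example by 0.77 for Kupffer cell, 0.59 for collecting duct and 0.57 for stromal genes. Erythroid and platelet (-3.00), monocyte (-1.19), T cell (-1.08) and dendritic cell (-0.83) genes were among those below their mean in mouse 2, also without passing. Mouse 2 also had more genes at 10 or more (10538, against 8840 in mouse 1 and 8751 in mouse 3) and above 0 (12853, against 12019 and 11883). The median over genes above 0 was 284 in mouse 2, 211 in mouse 1 and 245 in mouse 3.

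Of 29 gene pairs tested within libraries, 20 differed at an adjusted p under 0.05 (limma) and 26 had the same sign in 3 of 3 mice. In 5 of the 20, the second gene was at 0 in every mouse. With only the 24 other pairs in the fit, a choice made after the data were seen, 10 were called, against 15 of the same 24 in the fit of all pairs. Fcgr4/Fcgr1, Csf1r/Flt3 and H2-Ab1/H2-K1 were called under all 11 alternatives. Apoe/Trem2, Cd86/Cd80, Csf1r/Cd3e and Il1b/Il1rn were called under the 10 run on them, since the fit of pairs with both genes above 0 leaves them out. The other 13 lost their call without at least one mouse, and 10, 12 and 12 pairs were called without mice 1, 2 and 3. Without mouse 1, the lost calls had adjusted p from 0.0523 to 0.198 (limma), without mouse 2 from 0.0517 to 0.192 (limma), and without mouse 3 from 0.0511 to 0.130 (limma).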

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

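The counts of detected genes, of lists above random lists and of lists more variable than matched lists stayed within 1.5 times their main values under every alternative run. Detected genes ranged from 5093 at a minimum of 50 to 9476 at a minimum of 1, and the wording fixed beforehand, a deposited value of 10 or more, gave 6718 instead of 6572. Lists above random lists ranged from 9 to 17. The lists of macrophage identity, Fc gamma, MHC class I and class II, chemokine and lysosomal genes passed the test under all 12 alternatives. Lists below random lists (2) numbered 3 with a pseudocount of 0.1 and 3 with list means, where collecting duct genes were added, 0 to 2 without one mouse, with 0 without mouse 2, and 0 with random lists from genes at 10 or more in every library, a setting that by construction drops most of their members. Calls of gene pairs fell from 20 to between 10 and 12 without one mouse, as fewer samples carry the test. Among the 24 pairs with both genes above 0, calls fell from 15 to 10 when only these were fitted, which was chosen after seeing the data. The lowest Spearman correlation was between 0.613 and 0.634 without one mouse and 0.518 over genes detected in every mouse. These changes come from the set of genes, since the values of the libraries stayed the same. Between mice 1 and 2, rho was 0.654 over genes above 0 in any of the 3 mice. It was 0.634 without mouse 3, where genes at 0 in both other mice drop out. The median SD was between 0.898 and 0.999 without one mouse, as the SD of 2 values has a lower median by construction, 2.10 over genes above 0 in any mouse and 0.932 over genes at 50 or more in every mouse. None of the results below passed the threshold in either direction. The cause was not tested for any of them. The microglia list (-0.031 log2 units) turned to 0.024 with a pseudocount of 0.1, 0.34 with random lists from all rows, 2.61 with random lists from detected genes, 0.47 per kb of exon, 1.69 with list means, and -1.09 to 3.43 without one mouse (1.07 without mouse 3). Cytokines (0.17) turned to -0.018 with a pseudocount of 10, -3.27 with all rows, -0.67 with detected genes, and -1.15 to 0.17 without one mouse (-0.11 without mouse 3). Dendritic cell genes (0.11) turned to -3.09 with all rows, -0.11 with detected genes, -0.058 per kb, -0.82 with list means, and -0.38 to 1.55 without one mouse (-0.34 without mouse 3). Immediate early genes (-0.57) turned to 0.37 with detected genes, 0.15 per kb, 0.042 with list means and -0.91 to 0.18 without one mouse. Without one mouse, proliferation genes ranged from -1.06 to 0.72 and alveolar macrophage genes from -0.29 to 2.27. Monocyte genes turned to 2.28 with detected genes, and loop of Henle genes to -1.28 with detected genes and -0.23 per kb. The Cxcl2/Cxcl1 ratio (-2.03) ranged from -4.70 without mouse 2 to 1.19 without mouse 1. Of the other list results, 20 gained and 15 lost their call under an alternative, and 372 kept their side. Of the pair results, 7 gained and 38 lost their call. No paired analysis was possible because the labels give 1 group. Depth limits genes near the floor of 3 reads.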

Other observations

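The gene groups of this paragraph, and the tests of scaling and of a lower macrophage share in mouse 2, by cell type as well, were chosen after values had been seen. Of the C-type lectin receptors, many of which bind sugars, 9 of 11 measured were at 1000 or more in every mouse, led by Clec4a3 (42878 ± 16714), Clec12a (30023 ± 14299.5), Clec4a2 (29818 ± 8352) and Clec4b1 (18716 ± 1276), while Clec4d was at 0 in every mouse. Other receptors of immune cells included Lilrb4a (37804 ± 11069), Cd72 (35383 ± 15745), Cd33 (27002 ± 6656) and Lair1 (26289.5 ± 12002). Tgfbr1 reached 107145 ± 32715, and 4 of 9 TGF-beta receptor and signalling genes, 4 of 9 tetraspanins, 4 of 9 purinergic and adenosine receptors and 0 of 7 coagulation genes were at 1000 or more in every mouse. The groups carry no test, since they were picked after their values were seen.

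A set of 1130 genes was at 1000 or more in one mouse and at 10 or less in another, 18.2% of the genes at 1000 or more in any mouse. Counting error of sequencing reads is argued against by the gap between 10 and 1000 itself, which is too wide for it. The 100 Poisson redraws gave no more than 0 such genes, an outcome that these limits set in advance. An added cell type in one mouse is argued against as the whole cause, since the 313 genes high in a single mouse were split 109, 97 and 107, with a largest share of 34.8% (95% exact interval to 40.4%). Few RNA molecules of each transcript entering amplification may contribute: among genes at 10000 or more in the held-out mouse, 0 of 634, 0 of 350 and 0 of 527 differed this way between the other mice, against 76 of 2563, 295 of 4341 and 87 of 2680 at 100 to 1000, a largest ratio of 0. Any other cause that weakens with level would give the same, and no biological explanation was tested because the labels give 1 group.

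Proximal tubule genes were highest in mouse 2 for 15 of 16 genes, the one call when 111 tests of 37 lists in 3 mice were adjusted together (adjusted p = 0.0222, permutation test). With adjustment within each mouse, the low tubule genes (-1.88) and high erythroid and platelet genes (4.68) of mouse 3 passed too (adjusted p = 0.0296 for both, permutation test), and mouse 2 stood apart in genes at 10 or more (10538 against 8840 and 8751) and in mitochondrial reads (14.3% against 10.3% and 8.73%). The tubule values of mice 2 and 3 are not independent, as both are taken from the mean of the same 3 mice. Scaling of the mouse 2 library is argued against, since TMM factors and equal totals shifted that library by only 0.01 and 0.19 log2 units, while the list stood 2.13 above matched lists of the same library, the value that marks the pattern. A lower share of macrophage RNA in mouse 2 stays open. The 43 pooled markers of 5 other cell types lay 2.60 log2 units below the tubule list (permutation p = 0.0099). Of 8 lists, the myeloid ones (tubule minus list 2.93 for dendritic cells, 3.29 for monocytes) and the low endothelial list (2.52) passed (permutation test, adjusted p = 0.00680, 0.00272 and 0.00965). B cell (0.17), stromal (0.85), loop of Henle (0.47), collecting duct (-0.29) and podocyte (0.85) lists did not pass (adjusted p = 0.905, 0.478, 0.786, 0.902 and 0.478), nor did the 49 markers that are not myeloid (permutation p = 0.298). Macrophage identity genes deviated by -0.29 log2 units in mouse 2, against -0.25 in matched lists (adjusted p = 0.970, permutation test). They took 2.69%, 2.38% and 2.42% of the reads in mice 1, 2 and 3. These values show no large drop and cannot exclude a small one. More proximal tubule cells or tubule RNA in the mouse 2 sample is a candidate explanation as well: a second tubule list, led by Gpx3 (32459.5 ± 34312), stood 1.83 log2 units above matched lists, with 18 of 21 genes highest in mouse 2, but whether tubule cells passed the sort for macrophages, or their RNA was bound or taken up, was not tested.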
